A study of Mus musculus with 2 samples.

How the data were processed

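RNA of sorted CD69-positive DP thymocytes was measured in 2 libraries, 1 from mice labelled wild-type and 1 from mice labelled as a conditional knockout. Per the labels' protocols, total RNA was extracted with Trizol and 1 ug was used with a TruSeq RNA kit. Per the submitters' processing notes, reads were aligned with HISAT2 to mm10 (GRCm38). The HISAT2 version and read filters are not given in the sources used here. Per the file headers, the authors quantified annotated RefSeq transcripts with StringTie 1.3.3b, with no assembly of new transcripts. The deposited gene tables give TPM (transcript abundance scaled to a sum of 1000000 in each library), FPKM and coverage, and the deposited transcript tables give coverage, FPKM and TPM per transcript and coverage per exon. The authors' coverage is the mean read depth per base and is not scaled to library size. Whether reads were counted by strand is not given in the sources used here, so reads of overlapping genes and of near-identical copies cannot be told apart, and such genes are reported as uncertain.

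The tables hold 24532 gene IDs, of which 24462 were matched by ID to a symbol in the RefSeq gene table of GRCm38.p6 and 70 were not. Values of a gene ID listed at several loci were summed. TPM keeps no depth, so depth was taken from coverage. Coverage times length of transcripts with few reads lay near multiples of 202 bases, which is 2 mates of 101 bases. In the libraries labelled wild-type and KO, 25.5% and 26.1% of such transcripts were within 2 bases of a multiple, against 2.48% by chance. Read pairs were therefore estimated as covered bases divided by 202. The covered bases on annotated exons were 4199 and 5076 megabases. The 10 most abundant genes held 5.09% and 5.44% of TPM.

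Groups were taken from the labels. The comparison was log2((TPM + 1) in the library labelled KO / (TPM + 1) in the library labelled wild-type) for 12029 genes with at least 1 TPM in at least 1 library, which understates the change of genes with low levels. A gene was called higher or lower at a log2 fold change of 1 or more in size. This is a rule of size and not a test. Levels have 95% exact Poisson intervals from the estimated read pairs, ratios have exact binomial (Clopper-Pearson) intervals of the 2 counts, and the floor for a level of zero was 3 read pairs in that library. PCR copies are not independent molecules, so intervals and floors cover counting error only.

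There were 36 fixed gene lists with 1023 names, of which 34 were not matched. Names were matched by symbol, then by synonym, and 2 names of the mitochondrially encoded list, COX1 and COX2, were matched wrongly in this way to the nuclear genes Ptgs1 and Ptgs2, which were not measured and enter no value. A list with at least 5 measured genes was described by its median log2 fold change and by where this lay among the medians of 10000 random lists of the same size matched in 20 bins of mean log2(TPM + 1). Named genes were fixed by a rule: Nsrp1 and 5 sorting markers; the 12 highest and 12 lowest fold changes among genes with at least 5 TPM in at least 1 library, leaving out predicted genes, RIKEN clones, small RNAs, symbols that start with Rn, pseudogenes and antigen receptor segments; the 2 highest and 2 lowest members of each list; and, for isoforms, the 8 largest changes and a fixed set of genes. Members of this rule that the report does not name are in the same tables, and a few further list members, Trim12c, Macf1, Prmt1 and the genes that share reads with a named gene were named after their values were seen. Isoform shares are a transcript's TPM as a percent of its gene's, for genes with at least 10 TPM in both libraries, with a threshold of 25 percentage points. These rules, the lists and most alternatives were set before the data were examined.

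Exon depth was used in a comparison of parts of a gene that was chosen after seeing the data. For each gene the 3' terminal exon of its most abundant transcript was set against all other exonic bases, both as coverage scaled to TPM-equivalents. These other bases are called upstream here, but they come from all transcripts of the gene and can include other last exons. Their coverage was divided by the length of the most abundant transcript without its terminal exon. With several transcripts the upstream level is thus not a mean depth, though the same length was used in both libraries. Shared sequence was measured as the percent of 50-base words of a transcript that also occur, on either strand, in GENCODE M21 transcripts of another gene. The alternatives tried were the pseudocount, the filter on low values, FPKM, a rescaling by the median ratio, a rescaling without ribosomal protein genes, random lists matched also on transcript length, isoform thresholds, and exon depth without the terminal exon.

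Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The fold rule was tested on simulated read pairs for the 12029 genes with 50 changed genes of at least 10 TPM at each fold: it called 50 of 50 genes changed 3-fold and 50 of 50 changed 4-fold, 13 of 50 changed 2-fold and 0 of 50 changed 1.5-fold. Of 100 simulated lists without a shift, 6 lay outside the random range. No genome sequence and no reads were used here.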

Results

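The data are RNA-seq levels of CD69-positive double-positive (DP) thymocytes, the CD4 and CD8 co-expressing T cell precursors of the thymus that have gained CD69 after a T cell receptor signal. The cells were sorted from C57BL/6 mice aged 6 weeks. There were 2 libraries, 1 labelled wild-type (floxed Nsrp1 alleles without Cre) and 1 labelled as a conditional knockout, KO (the same alleles with CD4-Cre, which is active from the DP stage). Nsrp1 encodes NSrp70, a nuclear speckle protein linked to alternative splicing, and the comparison asks how its loss changes RNA levels and isoforms in these cells. Aligned reads covered annotated exons with 4199 megabases in the library labelled wild-type and 5076 megabases in the library labelled KO. With 1 library per genotype there is no replicate check of any difference, no test was made, and each 95% interval, exact Poisson for a level and exact binomial for a ratio, covers counting error only. Both libraries held RNA of cells of both sexes, at levels that differed, so sex and genotype cannot be told apart.

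Nsrp1 itself was at the same level in both libraries, so its RNA level gave no sign of the deletion that the KO label states. A deletion that leaves the RNA level unchanged is not excluded by this. Nsrp1 (gene ID 237859, chromosome 11, 77044292 to 77078437 in mm10, minus strand) stood at 29.7 TPM (27.7 to 31.9) in the library labelled wild-type and at 29.6 TPM (27.8 to 31.5) in the library labelled KO. Its log2 fold change was -0.0046, with a counting half-width of 0.13. Each of the 7 exons of its single annotated transcript was covered in both libraries, and the ratio of exon depth, library labelled KO over the other, ran from 0.827 to 1.08. The lowest ratio was that of exon 1, which held 3.56 and 3.79 estimated read pairs and has an interval of 0.145 to 4.17. The lower bounds for exons 2 to 7 were 0.512 or more. Exon 7, which holds the 3' untranslated region and most of the read pairs, had a ratio of 0.996 (0.898 to 1.11). The labels do not say which exon is floxed. Every direction given from here on is between the library labelled KO and the library labelled wild-type, and none can be assigned to a loss of Nsrp1 RNA.

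**Figure D1:**
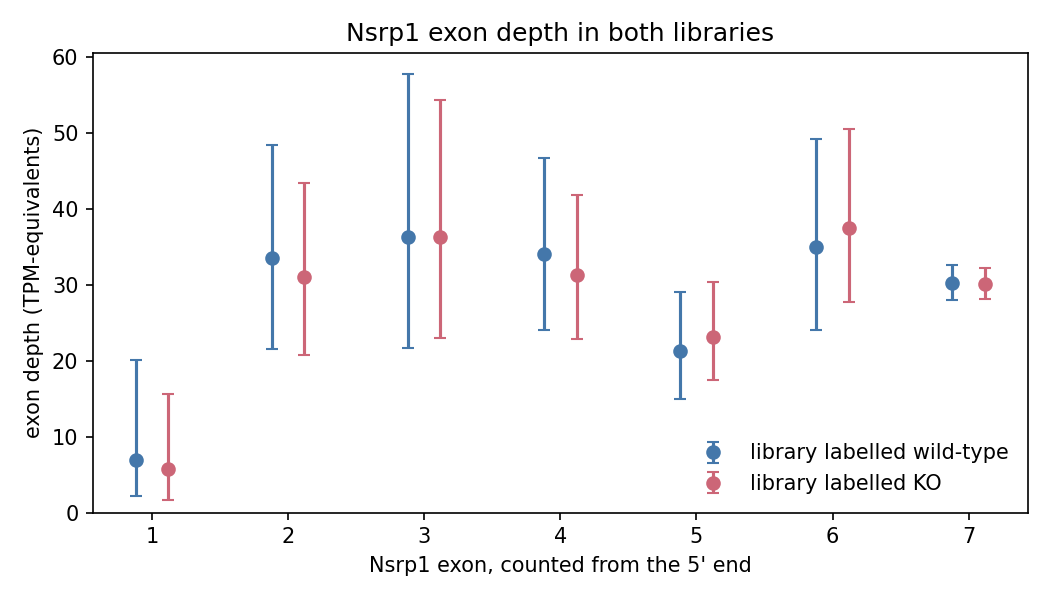
Depth of each Nsrp1 exon (x axis, counted from the 5' end) in TPM-equivalents (y axis) in the library labelled wild-type (blue) and the library labelled KO (red), with 95% exact Poisson intervals. The intervals of both libraries overlap at all 7 exons, and no exon is missing from the library labelled KO.

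The sorting markers were high in both libraries. Cd8a, which encodes a CD8 chain, stood at 1138 TPM in the library labelled wild-type and 1151 TPM in the library labelled KO, and Cd4 at 725 and 663 TPM. Cd8b1 was higher in the library labelled KO, with 1377 and 1679 TPM (log2 fold change 0.29), as was Cd69, with 430 and 522 TPM (0.28). Cd3e, a chain of the T cell receptor complex, stood at 944 and 862 TPM (-0.13). Rag1 and the other genes of the DP thymocyte programme had a median log2 fold change of 0.0049 over 25 measured genes, inside the range of matched random lists (-0.10 to 0.09). Within that list Aqp11 was the highest, with 65.2 and 114 TPM, followed by Dntt, which encodes terminal transferase, with 572 and 760 TPM. The lowest were Tcf7 with 1567 and 1276 TPM and Bcl11b with 263 and 217 TPM, both transcription factors of the T lineage.

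Across genes the libraries differed little, and the clearest difference of a gene group was a higher level of cell cycle genes in the library labelled KO. The largest single difference was the near absence there of the inducible heat shock genes Hspa1a and Hspa1b. Of 12029 genes with at least 1 TPM in at least 1 library, 79 were higher and 165 were lower in the library labelled KO by a log2 fold change of 1 or more in size. A further count puts this in scale: 10852 genes (90.2%) lay within 0.5 of zero on the log2 scale. Genes with a symbol that starts with Mir, Snor, Scarna or Rn made up 21 of the higher and 77 of the lower genes. This count by symbol was meant for small RNAs but can include other genes. The share of such symbols among all 12029 genes is not given here. In simulated libraries of this depth, 103 of 11829 unchanged genes passed the same rule through counting error alone. With at least 5 TPM in at least 1 library the counts were 46 higher and 83 lower, against 38 of 9708 unchanged genes in the simulation. With FPKM in place of TPM the split was 51 higher and 50 lower.

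Among the 12 lowest genes, Hspa1b and Hspa1a led. Hspa1b stood at 493 TPM (485 to 502) in the library labelled wild-type and at 0.558 TPM (0.316 to 0.869) in the library labelled KO, and Hspa1a at 467 TPM (459 to 476) and 0.525 TPM (0.293 to 0.833). Both encode the stress-inducible HSP70 and share most of their sequence, so their split is uncertain. Their summed level differed 887-fold (632 to 1276). Tns3, which encodes a focal adhesion protein, was 10.2-fold lower in the library labelled KO (67.1 and 6.61 TPM), with 18.2 and 2.88 TPM-equivalents upstream of its terminal exon, and Rab6b, a Golgi trafficking GTPase gene, was 6.84-fold lower (9.35 and 1.37 TPM). Hey1, a Notch target gene, stood at 5.39 TPM (4.41 to 6.55) and 0.656 TPM (0.372 to 1.06). The natural killer receptor ligand gene H60b stood at 9.94 and 2.80 TPM, and AA467197 at 12.1 and 3.46 TPM. The histone genes H1f3, with 11.4 and 3.08 TPM, and H4c18, with 19.5 and 5.86 TPM, rested on 26.7 and 23.9 estimated read pairs in the library labelled KO.

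A further 2 of the lowest genes differed mainly in the last exon or share reads with a neighbour. Znrf1, a ubiquitin ligase gene, stood at 450 and 152 TPM, and at a log2 fold change of only -0.36 upstream of its terminal exon. A share of 49.9% of the Znrf1 transcript's 50-base words also occurs in transcripts of Ldhd. Xndc1 stood at 26.9 and 7.13 TPM and shares 68.4% of its words with other genes, chiefly Xntrpc. The summed level of Xndc1 and Xntrpc was 29.0 and 14.2 TPM.

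Among the 12 highest genes in the library labelled KO were Gpx1, Birc5, Ifi44l, Atp6v0c and Trim12a, which were also higher upstream of the terminal exon, though 31.2% of the 50-base words of Trim12a and 32.5% of those of Atp6v0c also occur in other genes. Gpx1, which encodes the glutathione peroxidase that removes hydrogen peroxide, stood at 56.4 TPM (51.6 to 61.5) in the library labelled wild-type and at 214 TPM (205 to 222) in the library labelled KO. Birc5, which encodes survivin of the mitotic chromosomal passenger complex, was 2.89-fold higher (35.7 and 103 TPM). Ifi44l, an interferon-stimulated gene, stood at 3.42 TPM (2.42 to 4.69) and 12.2 TPM (10.47 to 14.2). Atp6v0c, a proton pump subunit gene, stood at 6.43 and 19.5 TPM. Trim12a stood at 39.7 and 121 TPM, and at 114 and 172 TPM summed with its paralog Trim12c.

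The other 7 of the highest genes rest on shared sequence or were higher in the terminal exon only. Evi2 was listed with under 1 read pair in the library labelled wild-type and at 41.8 TPM in the library labelled KO, at least 477-fold higher against a floor of 3 read pairs. It lies in the same place as Evi2a and Evi2b, and the summed level of these 3 genes was 89.0 and 75.7 TPM. Gstp2 was listed at 0 and 23.0 TPM, at least 49.9-fold higher against that floor, while the sum of Gstp1, Gstp2 and Gstp3 was 134 and 201 TPM (log2 fold change 0.58). H2ac19 was at least 27.9-fold higher, but its sum with its identical copy H2ac18 was 41.2 and 35.5 TPM. Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, stood at 16.3 and 273 TPM, with a log2 fold change of 5.34 in the terminal exon and -0.11 upstream of it. Ube2v1 (33.5 and 117 TPM), Szrd1 (30.02 and 79.6 TPM) and Urgcp (5.40 and 17.3 TPM) were also higher in the terminal exon only, with log2 fold changes of -0.04, -0.16 and -0.58 upstream of it, so that Urgcp was lower there. A share of 91.2% of the words of Ube2v1 occurs in other genes, chiefly Gm20431, which leaves its level uncertain.

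**Figure D2:**
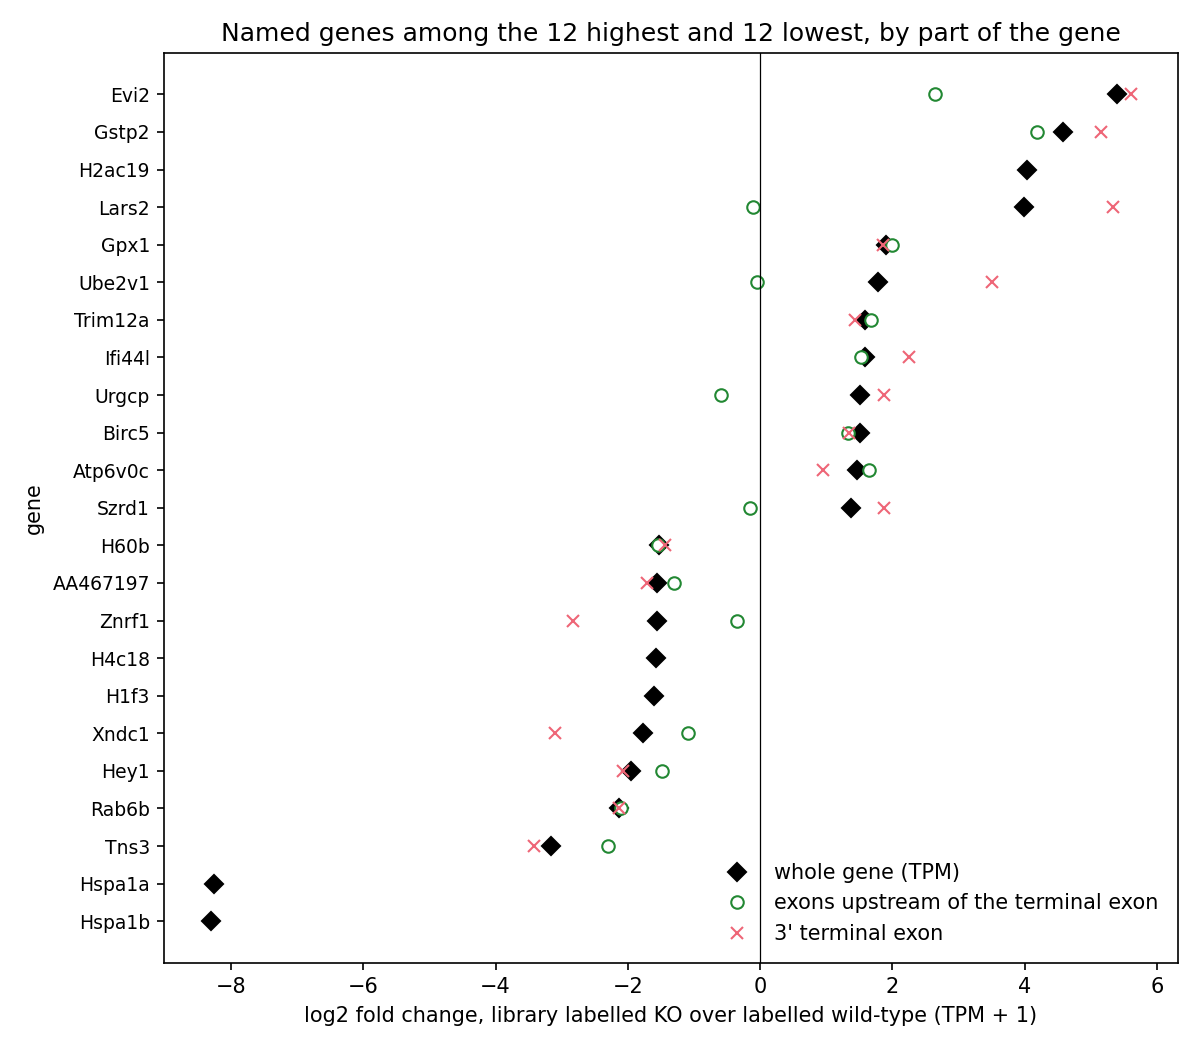
Log2 fold change (x axis, library labelled KO over library labelled wild-type, on TPM + 1) of genes named here among the 12 highest and 12 lowest (y axis) for the whole gene (diamonds), for the exons upstream of the terminal exon (open circles) and for the 3' terminal exon (crosses). Lars2, Ube2v1, Urgcp and Szrd1 lie below zero without the terminal exon, where the median of all genes is -0.14. Genes with a single exon have a diamond only.

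Terminal exons departed from the rest of their gene in many other places. Upstream stands for all exonic bases outside this exon, in any transcript of the gene, which can include other last exons. Upstream levels can be compared between libraries, but not with the terminal exon's level in genes with several transcripts. Of 8351 genes with at least 100 read pairs in each part, 50 had a terminal exon at least 2-fold higher relative to the upstream exons in the library labelled KO, and 50 at least 2-fold lower. Macf1, which encodes a cytoskeletal linker, had a terminal exon at 0.0708 and 175 TPM-equivalents, while its upstream exons stood at 104 and 69.6. Ptprc, which encodes CD45, had 22.7 and 1142 TPM-equivalents in the terminal exon and 1487 and 1308 upstream. The arginine methyltransferase gene Prmt1 had 76.8 and 1.297 in the terminal exon and 275 and 294 upstream. That exon is the last of NM_001252476, whose share of the TPM of Prmt1 was 82.6% and 23.2%. For Prmt1 a change between transcripts cannot be told apart from a difference of this exon alone. The median gene had terminal exons higher by 0.19 on the log2 scale in the library labelled KO, relative to its upstream exons. Upstream of the terminal exon the median log2 fold change over 11003 genes was -0.14, against -0.07 over the 12029 whole genes. Upstream values are therefore to be read against -0.14 and not against zero. Of 56 genes called higher that have a terminal and an upstream part, 36 were also higher by 1 or more upstream, as were 50 of the 75 called lower in their direction.

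Cell cycle genes were higher in the library labelled KO. G2/M genes had a median log2 fold change of 0.78 over 35 genes, against a random range of -0.17 to 0.01, and 34 of them were higher in the library labelled KO. Birc5 was followed by Tpx2, a spindle assembly gene, at 18.2 and 39.3 TPM. The lowest were Smc4, a condensin gene, at 492 and 369 TPM, and Kif23 at 34.4 and 40.3 TPM. G1/S and DNA replication genes had a median of 0.47 over 37 genes (random range -0.16 to 0.03), and 36 were higher. Rrm2, the ribonucleotide reductase subunit that limits nucleotide supply, stood at 50.5 and 112 TPM and the replication factor gene Gins2 at 7.58 and 14.98 TPM, while Rfc3 (48.8 and 48.1 TPM) and Dtl (16.0 and 16.1 TPM) were level. Without terminal exons the medians were 0.70 for G2/M and 0.43 for G1/S genes. Replication-dependent histone genes went the other way, with a median of -0.44 over 28 genes (random range -0.23 to 0.04), of which 22 were lower in the library labelled KO. This list was fixed as a marker of RNA quality. RNA quality and cell cycle were not separated here, so its difference cannot be assigned to either. H1f2 stood at 54.9 and 19.7 TPM and H1f3 was the lowest, while H3c3 (4.82 and 7.84 TPM) and H2ac4 (2.08 and 3.001 TPM) were higher.

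**Figure D3:**
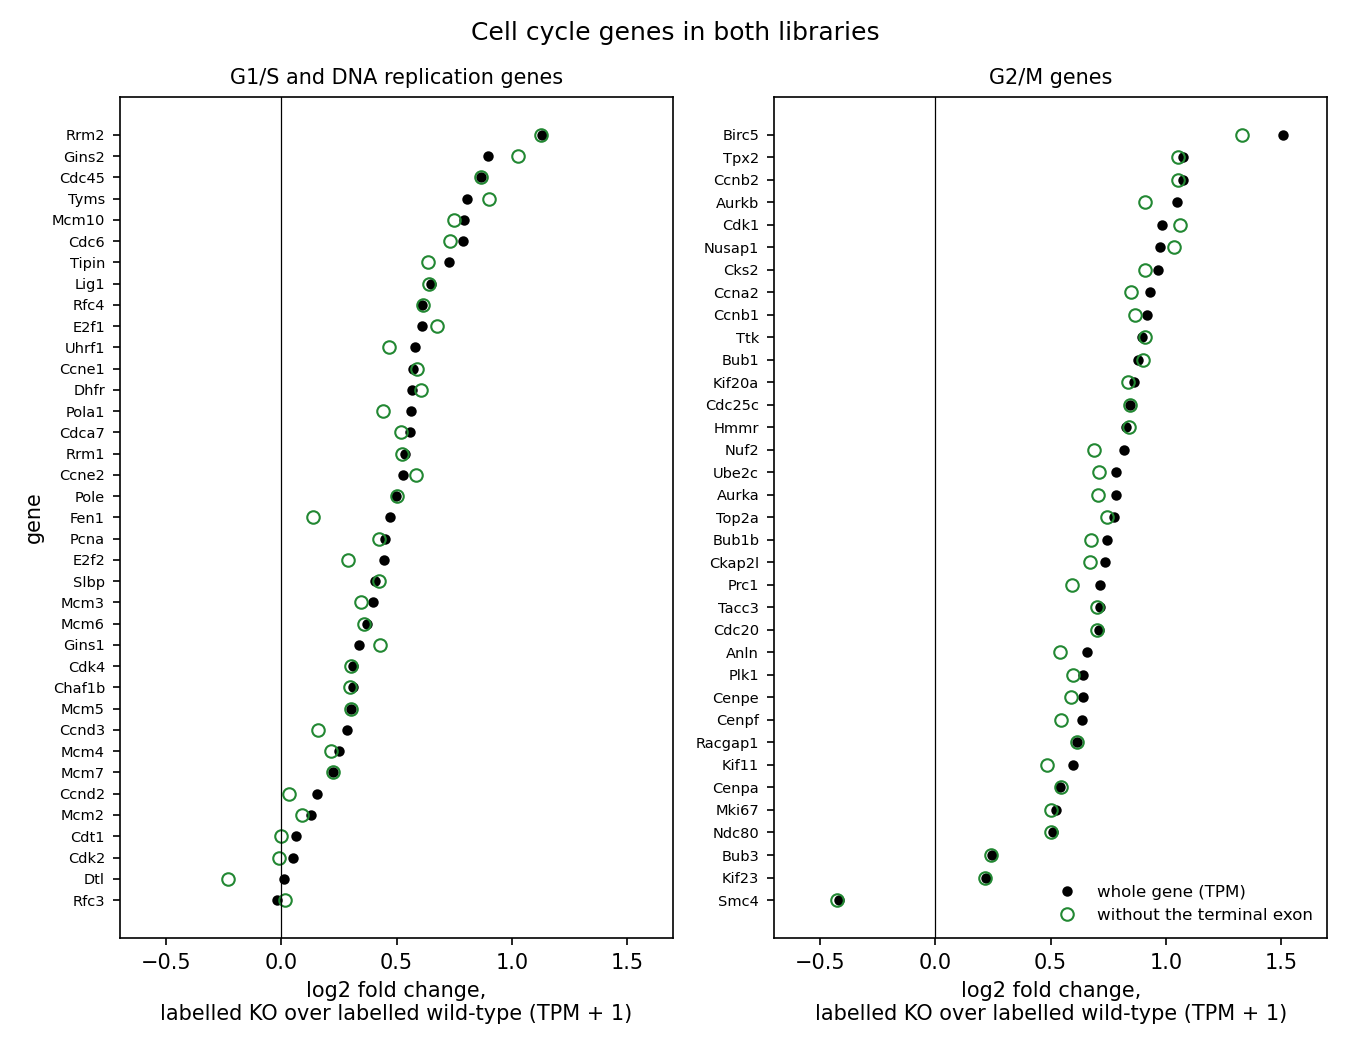
Log2 fold change (x axis, library labelled KO over library labelled wild-type, on TPM + 1) of the measured G1/S and DNA replication genes (left) and G2/M genes (right), for the whole gene (filled) and without the terminal exon (open). By whole gene, 36 of 37 and 34 of 35 points lie above zero, and Smc4 is the exception among G2/M genes.

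Of the 35 lists with at least 5 measured genes, 15 had a median outside the central 95% of 10000 random lists, 10 above and 5 below. The 10 above include the 5 sex-linked genes, of which 4 were above zero and Xist below, so that median describes no shared direction. Nuclear oxidative phosphorylation genes were higher in the library labelled KO, with a median of 0.19 over 46 genes (random range -0.04 to 0.09), 44 of them above zero. Random lists matched also on transcript length ranged from 0.07 to 0.16, so much of this difference was shared by other genes of such length. Cox5a (250 and 317 TPM) and Cox8a (416 and 526 TPM), subunits of cytochrome c oxidase, were the highest, and Ndufs1 (92.6 and 86.3 TPM) and Cyc1 (196 and 192 TPM) the lowest. Interferon-stimulated genes had a median of 0.19, with 28 of 35 genes above zero, among them Ifi44 (3.04 and 7.68 TPM) and Ifit1 (9.89 and 21.7 TPM). Without terminal exons their median was 0.09, with 21 of 35 above zero, and still lay above the random range of that setting (-0.29 to -0.03). Oasl2 stood at 4.36 and 2.84 TPM. Xaf1 was the lowest, at 51.5 and 18.6 TPM, but its log2 fold change upstream of the terminal exon was 0.0051. The MYC-linked ribosome biogenesis genes had a median of 0.07 over 31 genes, against a random range of -0.15 to 0.05. Without terminal exons the median of these 31 genes was 0.03, still above the random range of that setting (-0.24 to -0.0015). Srm (41.1 and 52.7 TPM) and Nop16 (29.6 and 37.4 TPM) were the highest of these, and Odc1, the first enzyme of polyamine synthesis (156 and 100.3 TPM), and Hspe1 (281 and 212 TPM) the lowest.

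Late maturation and egress genes were lower in the library labelled KO, with a median of -0.19 over 29 genes (random range -0.13 to 0.06) and 20 below zero. Samhd1, a nucleotide triphosphatase gene, stood at 56.9 and 24.2 TPM, and Klf2, a transcription factor that controls thymic exit, at 41.5 and 19.3 TPM. S1pr1, the sphingosine phosphate receptor used for that exit, stood at 8.28 and 3.61 TPM. Plac8 (32.1 and 41.7 TPM) and Ms4a4b (60.3 and 77.6 TPM) were the highest of the list. T cell receptor signalling components had a median of -0.13 over 37 genes (random range -0.08 to 0.08), a list that random lists matched also on transcript length no longer set apart. Cbl, a ubiquitin ligase that limits receptor signalling, stood at 165 and 90.7 TPM and Plcg1 at 207 and 146 TPM. Ptprc (939 and 1234 TPM) and Nfatc1 (120 and 148 TPM) were the highest. Upstream of the terminal exon their log2 fold changes were only -0.19 and -0.37, against a median of -0.14 over all genes.

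The heat shock and unfolded protein response genes had a median of -0.16 over 23 genes (random range -0.13 to 0.09), with 4 lower and none higher by 1 or more. Besides Hspa1a and Hspa1b these were Hsph1, a co-chaperone gene, at 147 and 68.0 TPM, and Hspb1 at 3.01 TPM and listed at 0. Hsp90aa1 stood at 580 and 319 TPM, Hspa8 at 2230 and 1881 TPM and Dnajb1 at 161 and 142 TPM. Dnajb9 (40.9 and 51.0 TPM) and Asns (0.840 and 1.23 TPM) were the highest. Without Hspa1a and Hspa1b the median of the other 21 genes was -0.05, inside the random range. The list also lay inside the range without genes under 5 TPM in both libraries, and without terminal exons. The latter setting leaves out this single-exon pair and gave a median of -0.17. Its random range, -0.22 to 0.06, was both lower and wider, and the median of all genes in it was -0.14. The immediate-early genes that respond to tissue dissociation, a list that also holds Hspa1a and Hspa1b, had a median of -0.06 over 17 genes, inside the random range. Junb (244 and 301 TPM) and Dusp1 (100.7 and 123 TPM) were its highest members.

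**Figure D4:**
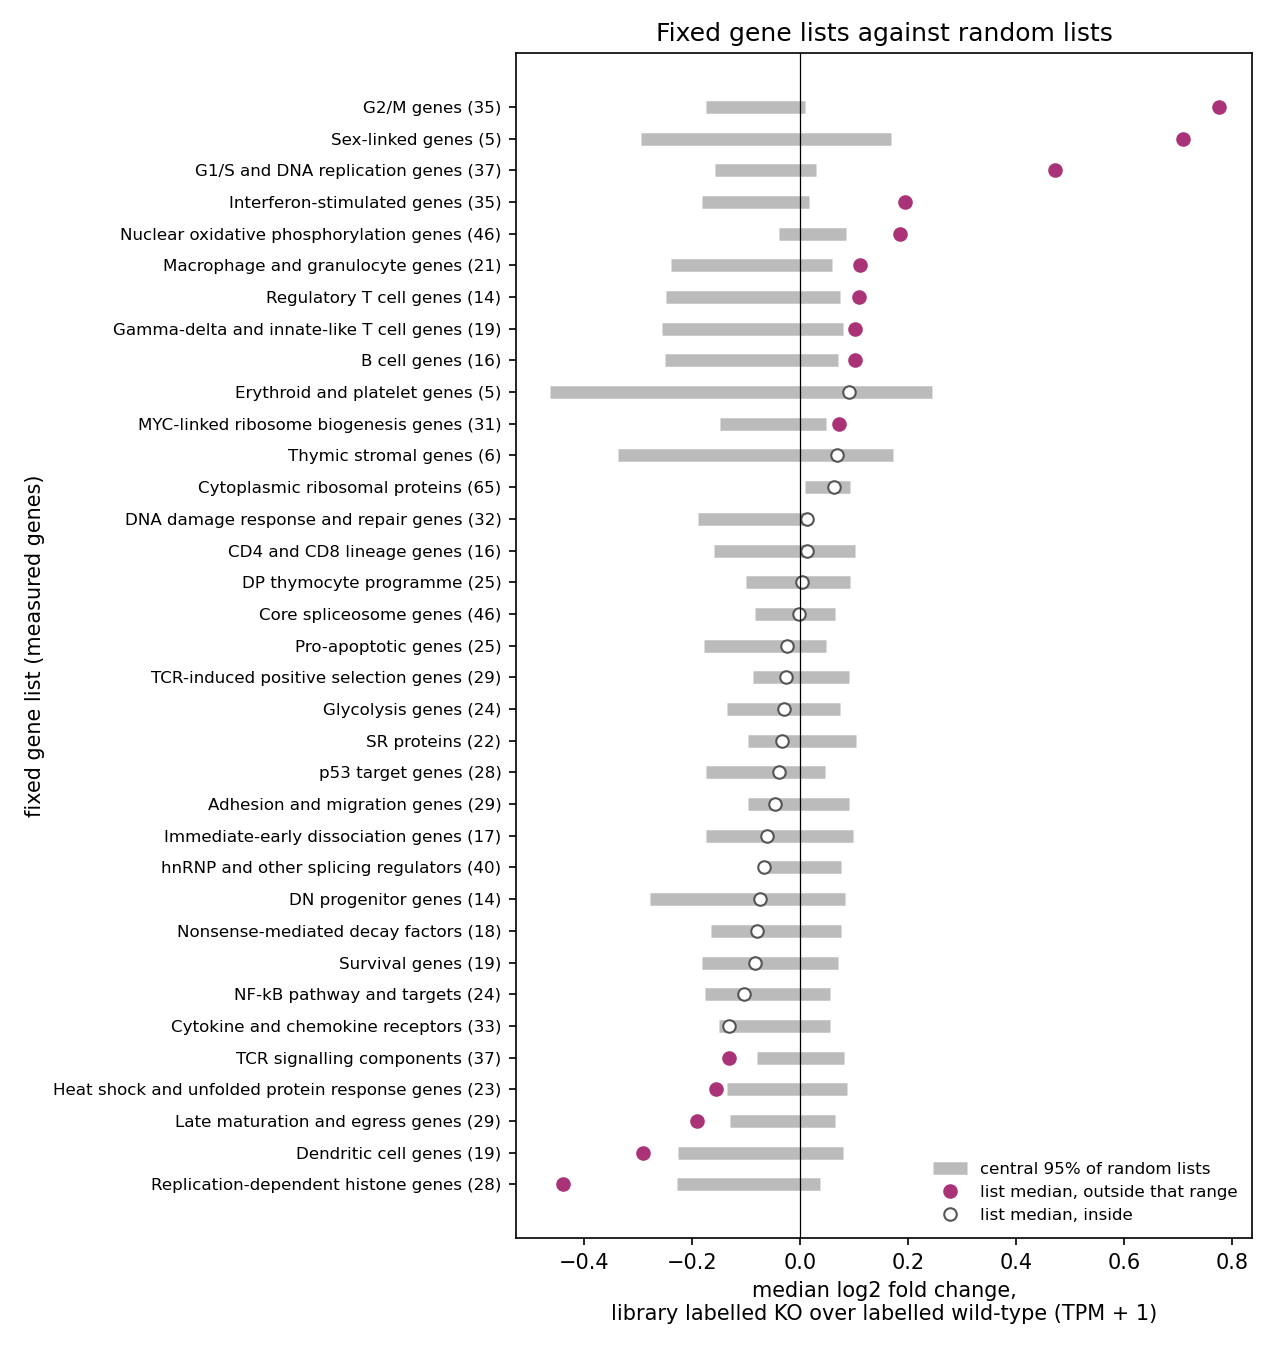
Median log2 fold change (x axis, library labelled KO over library labelled wild-type, on TPM + 1) of each fixed gene list (y axis, number of measured genes in parentheses). Grey bars span the central 95% of the medians of 10000 random lists of the same size and expression, filled points lie outside this range and open points inside. G2/M genes have the highest median, 0.78, and replication-dependent histone genes the lowest, -0.44.

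The splicing lists lay inside the random ranges. SR proteins, the serine- and arginine-rich splicing factors and their kinases, had a median of -0.03 over 22 genes. Srrm2, a nuclear speckle scaffold gene, stood at 322 and 216 TPM and Srrm1 at 158 and 124 TPM, whereas Srsf5 stood at 848 and 983 TPM. Tra2b stood at 163 and 262 TPM, but at a log2 fold change of 0.02 upstream of its terminal exon. The hnRNP and other splicing regulators had a median of -0.07 over 40 genes, with Rbm3 (760 and 905 TPM) and Mbnl3 (10.1 and 12.1 TPM) highest. Ptbp2 (68.7 and 49.8 TPM) was the lowest, followed by Hnrnpc (496 and 364 TPM), whose upstream exons differed by -0.03. Core spliceosome genes had a median of -0.00077 over 46 genes, from Snrpd1 (142 and 185 TPM) and Snrpf (154 and 198 TPM) to Snrnp70 (724 and 596 TPM) and Prpf8 (253 and 204 TPM). Nonsense-mediated decay factors had a median of -0.08 over 18 genes, from Rbm8a (64.9 and 76.2 TPM) and Magoh (224 and 261 TPM) to Upf1 (125 and 99.1 TPM) and Smg1 (143 and 106 TPM).

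Isoform shares were compared because the targeted protein is tied to splicing. Of 3032 genes with at least 10 TPM in both libraries and at least 2 annotated transcripts, 201 (6.63%) had a transcript whose share of the gene differed by 25 percentage points or more, and the median gene's largest difference was 5.11 points. These shares are the deposited estimates, and their error is not given. How many genes would pass this threshold between libraries of the same genotype is not known. The 8 largest differences were 71.3 points or more in size. For Tns1, transcript NM_027884 made up 0.0377% of the gene in the library labelled wild-type and 100% in the library labelled KO, and for Atp5pb, a subunit gene of ATP synthase, NM_009725 made up 0% and 99.1%. The share of NM_001134384 of Iqsec1 was 90.4% and 1.28%, that of NM_001281999 of Rasal1 0% and 80.5%, and that of NM_001039586 of Glyctk 0% and 79.3%. NM_001243075 of Cep57l1 had 78.1% and 0%, NM_001097623 of Trerf1 23.1% and 100%, and NM_008635 of Map7 71.3% and 0%. Of the 201 genes, 196 had a log2 fold change of the whole gene below 1 in size, and in 24 the terminal exon also departed by at least 2-fold from the upstream exons. Tra2b was the only 1 of 13 compared SR protein genes among the 201, Nfatc1 the only 1 of 20 compared T cell receptor signalling genes, and none of 31 other splicing regulators was among them. Tra2b and Nfatc1 both had such a terminal exon, higher relative to the upstream exons by 2.84 and 2.85 on the log2 scale in the library labelled KO. Their shares cannot be told apart from that pattern.

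Genes with well-studied splice forms differed by fewer points. The short standard form of Cd44, NM_001039151, made up 98.6% of the gene in the library labelled wild-type and 99.5% in the library labelled KO. The 3 transcripts of Ptprc had shares of 26.9%, 52.4% and 20.7% in the former and 22.8%, 55.7% and 21.5% in the latter. For Fas, which encodes a death receptor, the long transcript NM_007987 had 81.5% and 83.2%. The main transcript of Fyn had 90.5% and 92.9%, NM_001313981 of Tcf7 61.9% and 58.6%, and NM_001289716 of Bcl2l1 69.2% and 77.6%. For Lef1, NM_001276403 had 1.66% and 12.7%. The non-coding transcripts of Srsf3 (NR_036613) and Srsf7 (NR_036615) had lower shares in the library labelled KO, 46.2% and 37.0% for Srsf3 and 49.6% and 42.3% for Srsf7, and NM_001078167 of Srsf1 had 44.6% and 35.4%. The first transcript of Srsf5, NM_001079694, had 45.9% and 49.6%. Nsrp1, Mcl1, Malt1, Srsf2, Srsf4 and Srsf6 have 1 annotated transcript here and gave no share to compare.

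The remaining thymocyte lists lay inside their random ranges. TCR-induced positive selection genes had a median of -0.03 over 29 genes, with Itm2a at 1347 and 1830 TPM and the orphan receptor gene Nr4a2 at 9.89 and 5.57 TPM. CD4 and CD8 lineage genes had a median of 0.01 over 16 genes, from Nkg7 (35.2 and 52.4 TPM) to Runx3 (24.7 and 18.8 TPM). Pro-apoptotic genes had a median of -0.02 over 25 genes, with Bad highest (24.3 and 33.9 TPM) and Bmf lowest (57.9 and 31.4 TPM). Survival genes had -0.08 over 19 genes, with Bcl2a1b at 14.7 and 19.2 TPM and Bcl2l2 at 8.45 and 5.92 TPM. p53 target genes had -0.04 over 28 genes, and DNA damage response and repair genes 0.01 over 32. Cytoplasmic ribosomal proteins had a median of 0.06 over 65 genes, glycolysis genes -0.03 over 24, and NF-kB pathway genes -0.10 over 24, with Rel at 35.7 and 21.8 TPM. Cytokine and chemokine receptors had -0.13 over 33 genes and adhesion and migration genes -0.05 over 29. Without terminal exons the DP programme, TCR-induced, lineage and cytokine receptor lists lay below the range, with medians of -0.19, -0.17, -0.27 and -0.29, and ribosomal proteins above it at 0.06. With length matching the DNA repair genes lay above the range and the ribosomal proteins below it. None of the mitochondrially encoded genes had a row.

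Markers of other cells, of sex and of RNA quality also differed between the libraries. Dendritic cell genes were lower in the library labelled KO, with a median of -0.29 over 19 genes (random range -0.23 to 0.08). The class II antigen presentation genes Cd74 (199 and 148 TPM), H2-Aa (88.3 and 63.4 TPM), H2-Ab1 (72.2 and 48.6 TPM) and H2-Eb1 (55.6 and 36.7 TPM) were among them, while Bst2, also an interferon-stimulated gene, stood at 72.1 and 117 TPM. Small upward medians lay outside the random range for macrophage and granulocyte genes (0.11 over 21 genes), regulatory T cell genes (0.11 over 14), gamma-delta and innate-like T cell genes (0.10 over 19) and B cell genes (0.10 over 16). With random lists matched also on transcript length, the macrophage, gamma-delta and B cell lists lay inside the range. With a pseudocount of 5 TPM so did the dendritic cell and gamma-delta lists. The B cell list also lay inside it with at least 5 TPM in at least 1 library and with FPKM. The median of the regulatory T cell genes was -0.0486 without terminal exons, inside the random range of that setting (-0.38 to 0.05) and above the median of all genes there (-0.14). Within these lists Lyz2 stood at 59.5 and 43.6 TPM, Ctla4 at 14.1 and 6.65 TPM, Klrd1 at 3.82 and 6.88 TPM and Cd79a at 10.53 and 14.4 TPM. H2-Eb1 and H2-Ab1 are also the lowest members of the B cell list, in which 9 of 16 genes were above zero. DN progenitor genes, which mark the cycling double-negative stage before DP, had a median of -0.07 over 14 genes (random range -0.28 to 0.08), with the Notch receptor gene Notch3 lowest at 13.3 and 5.13 TPM and Kit at 2.91 and 1.57 TPM. Thymic stromal genes had a median of 0.07 over 6 genes, with Ctsl at 91.9 and 176 TPM, and erythroid and platelet genes 0.09 over 5. Both libraries held Xist, made in female cells, and Y-linked RNA. Xist stood at 201.8 and 76.3 TPM, Ddx3y at 31.1 and 71.2 TPM, Kdm5d at 15.4 and 31.0 TPM and Uty at 6.59 and 10.6 TPM, and the 5 sex-linked genes had a median of 0.71. Each library thus held RNA of cells of both sexes, with Xist lower and these Y-linked genes higher in the library labelled KO. A difference in the mix of sexes cannot be told apart from a difference of genotype. Long transcripts were lower in the library labelled KO, with a Spearman correlation of -0.36 between log2 fold change and transcript length across genes, which are not independent replicates.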

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

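The comparison without terminal exons was chosen after the data were seen and the other alternatives before. The counts of genes past the size threshold depended on the pseudocount and the filter. With a pseudocount of 0.1 TPM they were 139 higher and 305 lower, and with 5 TPM 21 and 34. With at least 5 TPM in at least 1 library they were 46 and 83, with at least 1 TPM in both 46 and 91, and with FPKM 51 and 50. The pseudocount and the filters act on genes with low levels, which depth limits most. Other settings kept the counts within 1.5 times of 79 and 165, and of the 56 higher and 75 lower genes with an upstream part, 36 and 50 were also called without terminal exons. The number of genes with a shifted isoform share was 61 at 50 TPM, 489 at 15 points and 61 at 40 points. The Nsrp1 log2 fold change stayed within counting error, from -0.0048 to 0.09, and 13 to 17 lists lay outside the random range in place of 15. Among named genes past the size threshold and lists outside the random range, the log2 fold changes of Lars2 (-0.11), Ube2v1 (-0.0405), Urgcp (-0.58), Szrd1 (-0.16) and Xaf1 (0.0051) and the median of regulatory T cell genes (-0.0486) changed sign without terminal exons. The difference of these 5 genes lay in the terminal exon. This setting also lowers the median log2 fold change of all genes, from -0.07 to -0.14. The regulatory T cell median was above that and inside its random range there (-0.38 to 0.05), so its sign alone shows no reversal. Of 34 list medians, 10 others moved under the setting without terminal exons, as did 47 of 149 named genes. Some that were smaller also changed sign, such as Ptprc, Nfatc1 and the medians of the DP programme and the CD4 and CD8 lineage genes. Values near zero can change sign through the lower median of all genes alone.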

Other observations

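Notch3 and Hey1, genes of the Notch pathway, which acts before the DP stage, were lower in the library labelled KO and are named by the fixed rule. Other genes of that pathway, picked after their values were seen, did not pass the size rule: Notch1 stood at 53.1 TPM in the library labelled wild-type and 39.1 TPM in the library labelled KO, Dtx1 at 9.78 and 7.81 TPM and Nrarp at 2.01 and 2.31 TPM. Malat1 and Actb were picked in the same way. The nuclear RNA Malat1 stood at 817 and 506 TPM and the actin gene Actb at 2884 and 3827 TPM.

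Of the tests used below to weigh 3 patterns, those of shared sequence and of the coding part of terminal exons were chosen before their values were seen, and the others after.

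Nsrp1 RNA was at the same level in both libraries. A swap of the 2 libraries is argued against only if the deletion removes most Nsrp1 RNA, which would leave it lower in the library labelled wild-type, whereas the ratio was 0.997 (0.908 to 1.09). A deletion of any exon from 2 to 7 in most cells is also argued against, since the lowest lower bound of their depth ratios was 0.512. A deletion of exon 1 stays open, with or without a swap, because its ratio of 0.827 rests on few read pairs. A wrong genotype label, a swap with a library outside this pair, alleles that had not recombined, RNA from cells without Cre, or a small deletion inside an exon may also apply and were not tested.

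Terminal exons departed from the rest of their gene in 100 genes, in both directions. More 3' coverage in 1 library would move nearly all of these genes 1 way, but 50% of the 100 went in the direction of the median gene. Over all 8351 genes the terminal exon was relatively higher in the library labelled KO, by a median of 0.19 (quartiles 0.05 and 0.32) on the log2 scale. A small general shift is thus present, but it runs against the 50 genes with a lower terminal exon. Shared sequence could account for part, since 12.1% of the searched genes (12 of 99) share over 50% of the terminal exon's words with another gene. A shorter 3' untranslated region stays open for the 75% of genes (69 of 92) whose terminal exon kept at least the depth its coding part needs, but 23 genes lay below it, such as Ptprc, with 1.74% of the relative depth where 14.2% of the exon is coding. Loss of reads at transcript ends during quantification and a difference of genotype were not tested.

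Hspa1a and Hspa1b were nearly absent from the library labelled KO. Exchange of reads between near-identical copies is argued against, since the summed level differed 887-fold. A loss of this pair's reads alone cannot be told apart from a wider difference. The other 21 genes of the heat shock and unfolded protein response list had a median log2 fold change of -0.05, inside the random range. That median cannot decide, since the list joins 2 responses and its members went both ways. Of all 23 members, with the pair, 17 were below zero and 6 above. The heat shock genes Hsph1, Hsp90aa1, Hspa8 and Dnajb1 were lower too, while Dnajb9 and Asns were the highest. Stronger stress during isolation of the cells labelled wild-type may also account for it, but the other 15 immediate-early genes had a median of -0.0498, inside the random range, with members on both sides. A variant allele of this locus and a difference of genotype were not tested.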
